A study of Mus musculus with 8 samples.

How the data were processed

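RNA was sequenced from the CA1 region of the hippocampus of 8 mice that express Cas9, each injected stereotaxically with an adeno-associated virus (AAV) carrying a guide RNA. In 4 mice the guide was against SIK3 (called KO here) and in 4 it was a control guide, with 2 males and 2 females in each group. Each mouse gave 1 library, so replicates are separate animals. Libraries are named by group and a number given in listing order, which pairs no animals. Per the labels' protocols, total RNA went through a TruSeq stranded mRNA kit. Virus lot, injection day, time after injection and library batch are not given in the sources used here.

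The authors deposited raw read counts per gene, 1 file per mouse, with 37315 Ensembl gene identifiers each and 0 entries that name no gene. Per the submitters' processing notes, Trimmomatic 0.33, TopHat2 2.1.1, HTSeq 2.0.1 and the build mm10 were used, with no role or order stated. The strand setting of the counting, the annotation release and any filter are not given in the sources used here. A further table with 8 columns was not used here. Without a stated strand setting, counts of genes that overlap on opposite strands are uncertain, and reads of near-identical copies, such as the MHC class I genes or Ifit3 and Ifit3b, may be split or lost in counting. Symbols were found for 35449 identifiers; the 1866 without one held 0.263% of all counts and kept their identifier. Positions, GC content and transcript lengths came from GENCODE release M21 on GRCm38.

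Totals ran from 13561662 to 18619928 counts. The males had 13561662 to 15165413 counts and the females 16743701 to 18619928, so depth and sex go together, while both guides have both sexes. Pairs of libraries, within and between groups, differed by 3.44 to 16.7 times the counting variance (chi-square per degree of freedom), so no library was a copy of another.

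Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group with a minimum count of 10 and a minimum total of 15, quasi-likelihood F test), with sex as an additive covariate. This kept 14788 genes, with 5 residual degrees of freedom. Calls were made at a Benjamini-Hochberg adjusted p of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Further fits gave the interaction of sex and guide and the guide effect within each sex from 2 mice against 2, with the spread shared over 8 libraries. CPM values were computed here from the counts and TMM library sizes, and log2 CPM used a prior count of 2.

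Gene lists for SIK3 pathways, activity, synapses, channels, stress, immunity and cell types were written before the data were examined, as were the groups, the tests and most of the alternatives. The 38 lists with at least 5 tested members, apart from the sex check, were tested with limma 3.58.1 camera at a preset correlation of 0.01. Camera with an estimated correlation, fry and an exact two-sided permutation of list means were set beside it. With 4 against 4 there are 70 assignments and the smallest permutation p is 0.0286.

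The rule for named genes took Sik3 and the sex-linked check genes, then up to 15 genes per direction past the adjusted p with a mean CPM of at least 1 and no overlap between the groups. With fewer than 5 such genes in a direction, the 5 with the smallest unadjusted p that met the other conditions were named as not past the threshold. Members with the smallest p were taken from each list. Predicted models were counted and not named, apart from Gm43302, Gm43802, Gm47283 and G530011O06Rik. The 6 genes called within females, the genes called between the sexes, and the immunoglobulin and low-count immune genes were named after their values were seen.

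Alternatives were other scalings (RLE and upper quartile), other filters or none, DESeq2 1.42.0, limma voom, svaseq from sva 3.50.0, a test against a 1.2-fold change, covariates, and leaving out each library. The slope of log2 CPM on GC content as a covariate, the permutation of list means, leaving out both KO females, and alternatives for the list interaction were added after seeing the data. The procedure was tested on simulated counts for 14591 genes at this sample size. Of 50 genes changed at each size, it recovered 40% at 1.25-fold, 68% at 1.5-fold, 90% at 2-fold and 94% at 3-fold, and it called 12 unchanged genes. It called 0 genes when nothing was changed. A list shifted by 0.4 log2 units was recovered with 0 other lists. Simulated genes were drawn independently of each other, without differences shared by whole libraries. The simulation therefore cannot show how camera at the preset correlation behaves when list members vary together. The recovery rates for genes also may not hold in the real libraries, which differed in their slope of log2 CPM on GC content. In the real libraries the estimated correlation was 0.58 for interferon-stimulated genes.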

Results

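Poly(A) RNA from CA1 was measured in 8 Cas9 mice, 4 given an AAV with a SIK3 guide (KO) and 4 given an AAV with a control guide, each group with 2 males and 2 females. SIK3 is a salt-inducible kinase, activated by LKB1, that phosphorylates the CREB coactivators CRTC and class IIa histone deacetylases. The libraries held 13561662 to 18619928 counts, and mitochondrially encoded genes took 8.53% to 9.84% of them. Pairwise correlations of log2 CPM were 0.985 to 0.993 within groups and 0.985 to 0.993 between groups, so libraries of one group were no more alike than libraries of different groups. Xist, the X-inactivation transcript, was at 1812 CPM on average in females and 0.434 CPM in males, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in the females, which matches the labelled sex of all 8 mice.

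The first question was what the SIK3 guide did to the targeted transcript. Sik3 (ENSMUSG00000034135, chromosome 9, 46012820 to 46224194 on GRCm38, plus strand) was at 147 ± 12.8 CPM in controls (SD, n = 4) and 86.2 ± 9.73 CPM in KO mice (SD, n = 4). Per library it was 165, 148, 139 and 137 CPM in controls 1 to 4, and 75.3, 88.3, 82.9 and 98.4 CPM in KO 1 to 4. It fell in KO mice, with a log2 fold change of -0.77 ± 0.09 (SE; edgeR quasi-likelihood test, adjusted p = 0.0202). The groups did not overlap (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows). The log2 fold change was -0.90 in males and -0.65 in females, and the difference between the sexes did not pass (edgeR, adjusted p = 0.765). The place of the guide in the gene is not given in the sources used here, and gene counts do not show whether the remaining transcripts carry an edit. Among the 11 tested genes within 500 kb of Sik3, which include the secretase gene Bace1 (log2 fold change -0.023), 0 had an unadjusted p under 0.05. The edgeR call of Sik3 was lost without control 2 (adjusted p = 0.108), control 3 (0.0866), KO 2 (0.0865) or KO 3 (0.242), with log2 fold changes of -0.77, -0.80, -0.80 and -0.75. It was also lost with dentate markers as a covariate (adjusted p = 0.0766), against a 1.2-fold change (0.182) and without both KO females (0.0990).

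**Figure D1:**
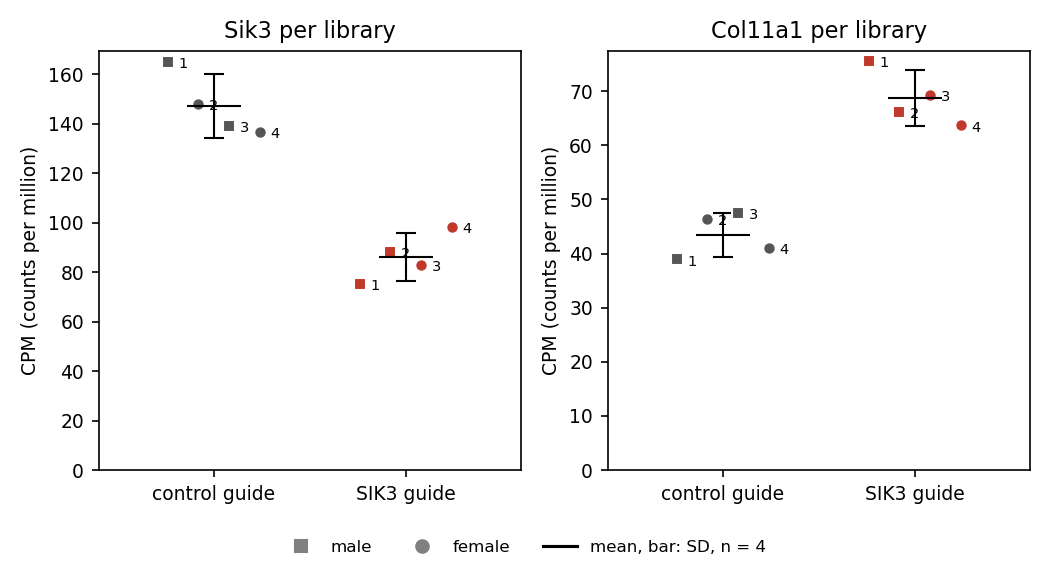
CPM of Sik3 and Col11a1 in each library, by guide; squares are males, circles females, numbers the library, and the bars give the mean and SD (n = 4). The 4 KO libraries lie below all controls for Sik3 (means 86.2 and 147 CPM) and above all controls for Col11a1 (68.7 and 43.4 CPM).

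The second question was which other transcripts differed between the guides. Across 14788 genes, 2 passed the edgeR test, Sik3 and Col11a1. Col11a1 (ENSMUSG00000027966, chromosome 3, 114030540 to 114220718), which encodes a fibrillar collagen chain, rose from 43.4 ± 4.14 CPM in controls to 68.7 ± 5.16 CPM in KO mice (SD, n = 4 each), a log2 fold change of 0.66 ± 0.08 (SE; edgeR, adjusted p = 0.0252). It was higher in all 4 KO libraries than in every control. The next adjusted p was 0.868. At an unadjusted p under 0.05 there were 416 genes, 264 higher and 152 lower, against 739 from chance alone, and 258 genes (138 higher, 120 lower) had groups that did not overlap, 1.74% of genes against 2.86% from chance. Libraries differed in their slope of log2 CPM on GC content, from -0.16 to 0.16 per 10 percentage points, with both signs in each group. DESeq2 and limma voom also called 2 genes, which were the same 2. The count was 84 with no filter on low counts and 0 with dentate markers as a covariate, against a 1.2-fold change, or without control 2, control 3, KO 2 or KO 3. It was 1 without control 4, where Col11a1 had an adjusted p of 0.205. With no filter the 84 calls were not only genes that the filter had removed. B2m, H2-D1 and Nlrc5, tested but not called in the main fit, were among them, and Sik3 had an adjusted p of 2.34e-23 (edgeR). The smallest p there were those of Igkc, Ighg2c, Ighg2b and Igha, which were high in KO 4 alone. The log2 fold changes of Col11a1 stayed close to the full value where its call was lost, at 0.71 without control 2 or control 3, 0.64 without control 4, 0.68 without KO 2, 0.65 without KO 3 and 0.67 with the dentate covariate, where Sik3 was at -0.75.

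Genes next in order did not pass and are given as values. The 5 with higher levels in KO mice were the guanylate-binding protein gene Gbp7 (log2 fold change 0.67 ± 0.13), the MHC class I gene H2-Q6 (1.61 ± 0.33), the MHC class I transactivator Nlrc5 (1.49 ± 0.31), Trim30a (0.78 ± 0.18) and Lgals3bp (0.92 ± 0.22), all with edgeR adjusted p of at least 0.943. The 5 with lower levels were Tmem126a (-0.35 ± 0.09), the neuronal transcription factor Neurod1 (-0.30 ± 0.08), the ATP synthase subunit gene Atp5e (-0.48 ± 0.13), Phyhd1 (-0.63 ± 0.17) and Zfp566 (-0.52 ± 0.15), all with adjusted p near 1. Gbp7 shares exon sequence on the same strand with the model Gm43802, and Neurod1 with Cerkl. Phyhd1 and Zfp566 share such sequence with predicted models.

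The third question was whether genes of a pathway or cell type moved together. Interferon-stimulated genes rose as a list: all 23 tested members had positive log2 fold changes, with a median of 0.79 (camera at a preset correlation, adjusted p = 1.56e-24). The call was lost when the correlation was estimated (adjusted p = 0.372), and 0 of the 23 passed over all genes while 15 passed adjusted over the list alone. Ifit3b, of the interferon-induced tetratricopeptide family, went from 3.06 ± 0.383 to 6.28 ± 3.19 CPM (SD, n = 4 each), and Lgals3bp had a log2 fold change of 0.92 ± 0.22. The list's mean log2 CPM, with the control mean set to 0, was 0.39, 0.36, 1.52 and 0.54 in KO 1 to 4 and -0.066 to 0.081 in controls (exact permutation p = 0.0286, adjusted p over 38 lists 0.724). The median was 0.52 without KO 3 and 0.38 without both KO females. Beside it, complement and MHC genes were high in both KO females and microglia markers in KO 4.

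Complement and MHC genes rose as a list, with all 15 tested members positive and a median of 0.42 (camera, adjusted p = 8.57e-10; adjusted p = 0.449 with an estimated correlation). In this list 0 members passed over all genes and 6 passed adjusted over the list alone. B2m, the light chain of MHC class I, was at 47.7 ± 1.84 CPM in controls and 70.1 ± 20.2 CPM in KO mice (SD, n = 4 each). The list score was -0.017 and 0.18 in the KO males and 0.69 and 0.97 in the KO females. T cell and monocyte markers, too low to test, held 64 raw counts in KO 4, 35 in KO 3, 25 and 24 in the KO males and 11 to 20 in controls. Immunoglobulin genes held 2446 in KO 4, 253 to 364 in the other KO libraries and 206 to 348 in controls. Ighm alone held 453 of these in KO 4, 238 to 332 in the other KO libraries and 198 to 327 in controls. Outside KO 4 most immunoglobulin counts were therefore Ighm. The median was 0.65 without control 1, and -0.028 without both KO females.

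Microglia markers also rose by camera, with 16 of 17 members positive and a median of 0.17 (adjusted p = 0.000521; adjusted p = 0.636 with an estimated correlation). Of these markers, C1qa, C1qb and C1qc are also members of the complement and MHC list. The fractalkine receptor gene Cx3cr1 had a log2 fold change of 0.19 ± 0.08, which did not pass. Their score was 0.42 in KO 4 and 0.041 to 0.10 in the other KO libraries, and without KO 4 the median was 0.041 and the call was lost (adjusted p = 0.198). Without both KO females it was -0.028. Meningeal fibroblast markers, which did not pass with all 8 libraries, were also highest in KO 4, at a score of 0.52. Their score ran from -0.13 to 0.24 in the other KO libraries and from -0.24 to 0.30 in controls. Reactive astrocyte genes had 16 of 18 members positive and a median of 0.16 (camera, adjusted p = 0.00413; adjusted p = 0.449 with an estimated correlation). Within that list Gbp2 had a log2 fold change of 0.95 ± 0.24 and Serpina3n, an acute-phase protease inhibitor, -0.19 ± 0.07, and neither passed. Gbp2 is also a member of the interferon list. At an unadjusted p under 0.05 (edgeR), 1 member of the reactive astrocyte list was higher, which was Gbp2, and 1 was lower. Astrocyte markers, a separate list, had a median of 0.016 and did not pass. The call was lost without KO 1 (median 0.16, adjusted p = 0.181) or both KO females (0.041, adjusted p = 0.589), and the median was 0.10 without KO 4.

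**Figure D2:**
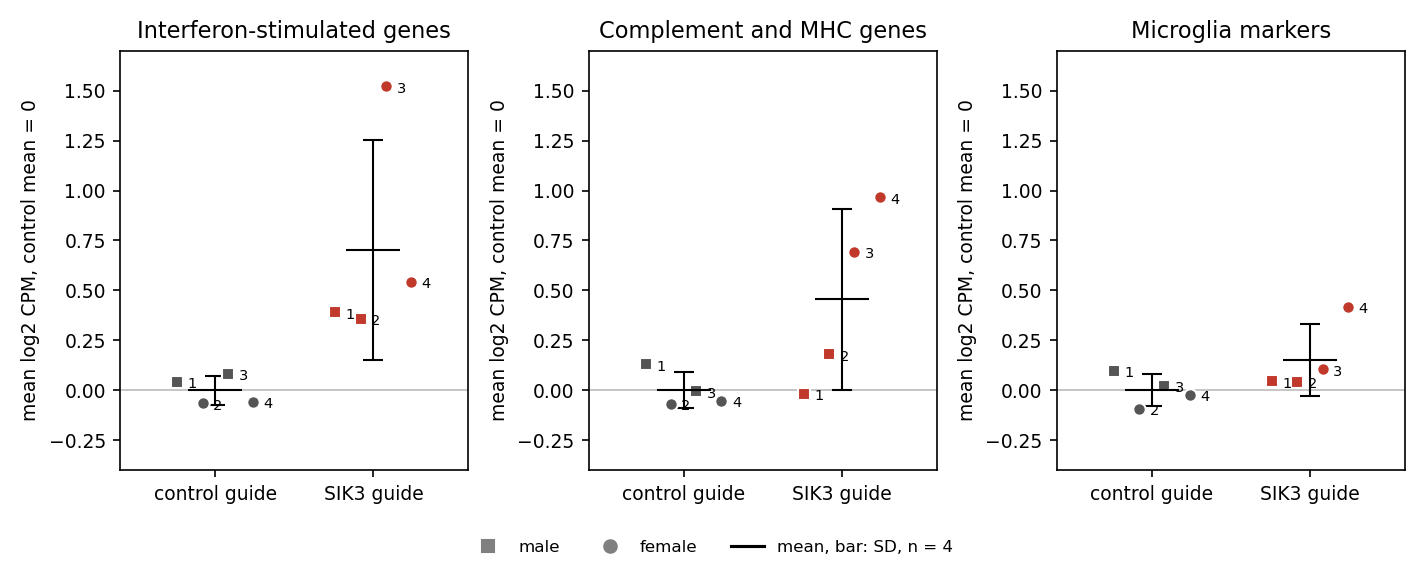
Mean log2 CPM of 3 gene lists in each library relative to the control mean; squares are males, circles females, numbers the library, and the bars give the mean and SD (n = 4). KO 3 stands at 1.52 for interferon-stimulated genes, KO 4 at 0.97 for complement and MHC genes and at 0.42 for microglia markers.

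The other lists past camera moved by less. Oligodendrocyte markers fell, with 15 of 16 members negative and a median of -0.14 (adjusted p = 0.00374; adjusted p = 0.785 with an estimated correlation); the myelin genes Mal and Cldn11 had log2 fold changes of -0.30 ± 0.15 and -0.36 ± 0.19. Their scores ran from -0.42 to 0.35 in controls and from -0.48 to 0.15 in KO mice, and the call was lost without control 1 (median -0.041), control 2 (-0.069), KO 2 (-0.00058) or KO 3 (-0.091), and with dentate markers as a covariate (-0.054, adjusted p = 0.127). The median was -0.29 without control 4, -0.30 without KO 4 and -0.32 without both KO females. Endothelial and pericyte markers rose by a median of 0.064 (camera, adjusted p = 0.00413; adjusted p = 0.372 with an estimated correlation), with Vtn at 0.34 ± 0.09 and the VEGF receptor gene Kdr at 0.21 ± 0.09, and the call was lost without control 1 (0.071) or KO 1 (0.031); without both KO females the median was 0.098. Interneuron markers fell, with 14 of 16 negative and a median of -0.066 (camera, adjusted p = 0.0107; adjusted p = 0.636 with an estimated correlation), and lost the call without control 1 (-0.051), control 4 (-0.052) or KO 1 (-0.051), with a median of -0.13 without both KO females. Circadian clock genes had a median of -0.045 (camera, adjusted p = 0.0257, and 0.372 with an estimated correlation), with the clock output factor Hlf at -0.12 ± 0.05 and Bhlhe41 at -0.20 ± 0.07. Their call was lost without control 1 (-0.050), control 2 (-0.039), KO 1 (-0.029), KO 4 (-0.034) or both KO females (-0.053, adjusted p = 0.365), and with dentate markers as a covariate (-0.035, adjusted p = 0.0864); without control 4 the median was -0.018. With an estimated correlation, by fry (smallest adjusted p 0.088) or by exact permutation, 0 of the 38 lists passed. The permutation could hardly have called any list, because its smallest p of 0.0286 was adjusted over 38 lists. Only 1 list reached that value.

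With all 8 libraries, lists tied to SIK3's known substrates and to neuronal activity did not pass camera, but some calls depended on single libraries. CREB/CRTC target genes had 18 of 22 members positive and a median of 0.063 (adjusted p = 0.219), with Crem at 0.25 ± 0.10, and passed without control 4 (median 0.12), KO 1 (0.16) or KO 3 (0.15), while the median was -0.0040 without KO 2 and -0.0048 without KO 4. MEF2 target genes had a median of 0.044 (adjusted p = 0.436), with Lgals1 at 0.48 ± 0.20, and the median was -0.0011 without KO 2 and 0.086 without control 4. The median was -0.017 for immediate early genes (adjusted p = 0.412). The immediate early genes passed as lower without KO 2 (-0.13), KO 4 (-0.17) or both KO females (-0.13) and with the GC slope as a covariate (-0.092), and had positive medians, which did not pass, without control 3 (0.032), control 4 (0.0085), KO 1 (0.061) or KO 3 (0.096). Of the 30 lists that did not pass, 12 gained a call when 1 library was left out, among them GABA receptor subunits without KO 1 (-0.086) and dentate markers without control 4 (-0.045) or KO 3 (-0.032). GABA receptor subunits also passed without both KO females. Their median had opposite signs in the sexes, at 0.060 in males and -0.15 in females. Of the SIK and LKB1 pathway genes, Sik3 passed and the other 20 tested did not. Glutamate receptor genes had a median of 0.0087, postsynaptic scaffolds of 0.019, synaptic vesicle genes of 0.019, potassium channels of -0.0016 and GABA receptor subunits of -0.0079, with camera adjusted p from 0.436 to 0.920. Kcna1, a delayed-rectifier potassium channel, had a log2 fold change of -0.13 ± 0.06, Cacng3 of -0.16 ± 0.07 and Lrrtm4 of -0.23 ± 0.10. Markers of CA1 (0.059), CA2 (0.043), CA3 (0.015) and dentate neurons (-0.0084) did not pass, with Rgs14, a CA2 gene, at 0.22 ± 0.07. The CA2 list had a mean log2 fold change of -0.012, against its median of 0.043. Its score was 0.20 in KO 1 and -0.12 to -0.046 in the other KO libraries. Medians of the lists that did not pass ran from -0.060 for oligodendrocyte precursor markers to 0.16 for meningeal fibroblast markers. Both ends depended on the setting. Meningeal fibroblast markers passed camera without control 1, control 2, KO 2 or KO 3, and with a mean CPM of at least 1 (median 0.18). Oligodendrocyte precursor markers passed without KO 4 or both KO females, and with the GC slope as a covariate. T cell and monocyte markers had 0 tested members and red blood cell genes 2, so those lists were not tested.

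**Figure D3:**
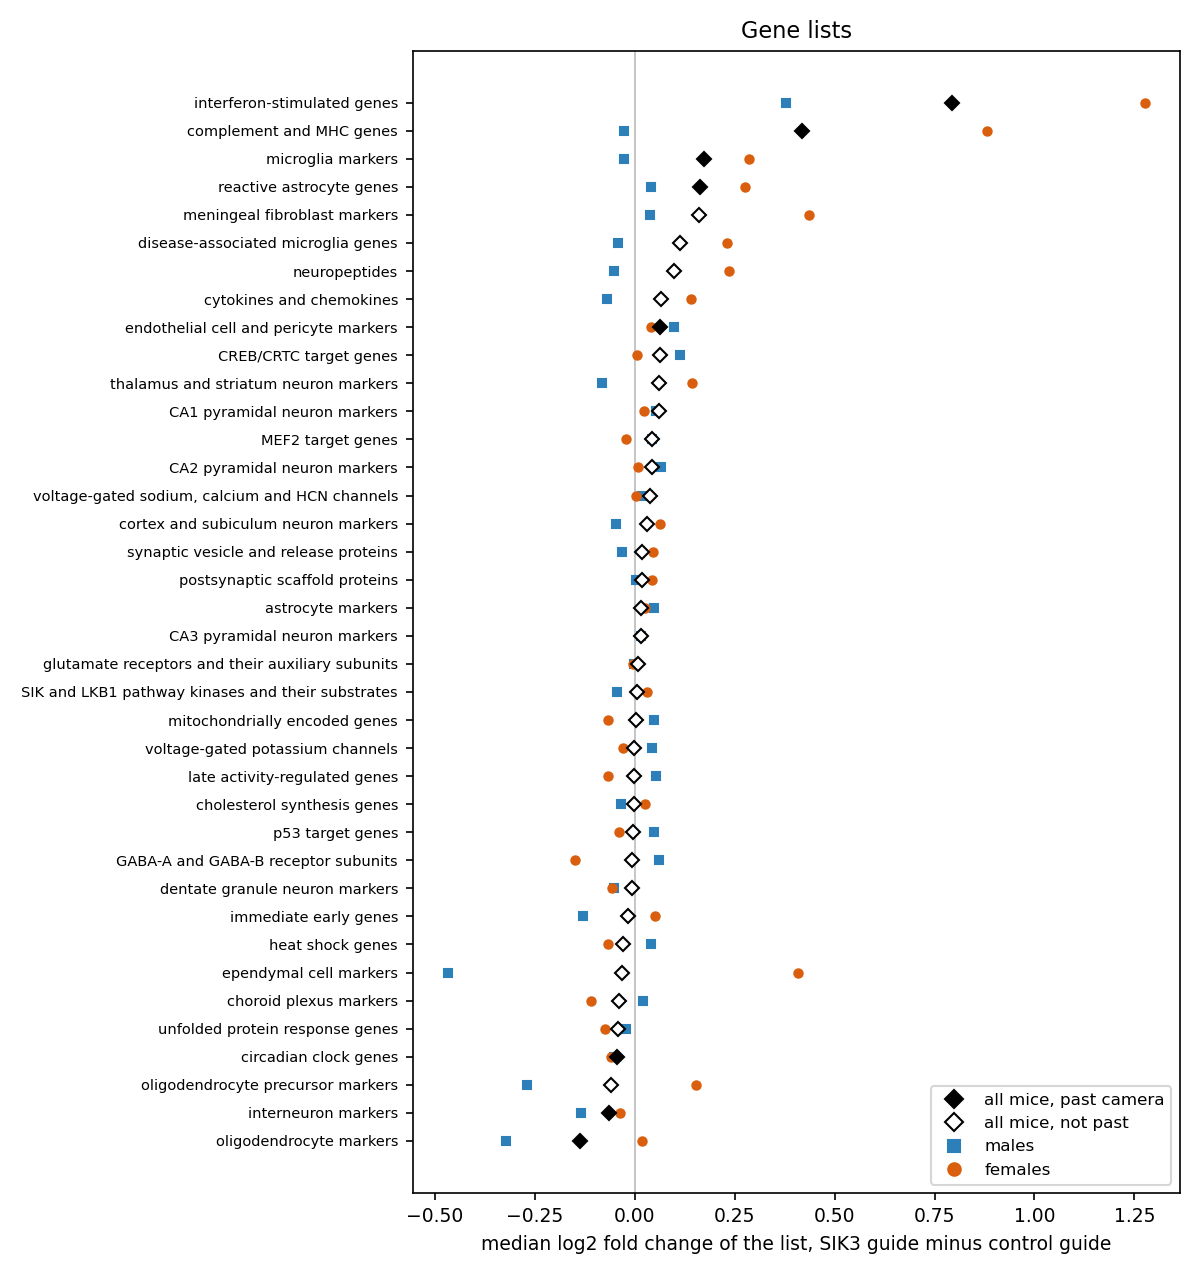
Median log2 fold change of the 38 tested lists, SIK3 guide minus control guide; diamonds are all mice (filled when past camera at the preset correlation), squares males and circles females. Interferon-stimulated genes lie at 0.38 in males and 1.28 in females, and complement and MHC genes at -0.028 and 0.88.

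The fourth question was whether the effect of the guide differed between the sexes. Within females, 6 genes passed and all were higher in KO mice: the MHC class I genes H2-D1 (log2 fold change 1.57 ± 0.15) and H2-K1 (1.54 ± 0.16), B2m (0.88 ± 0.10), the interferon-inducible GTPase gene Igtp (1.73 ± 0.23), Nlrc5 (2.13 ± 0.30) and the model Gm43302 (2.17 ± 0.25). These were chosen after their values were seen, and their edgeR adjusted p ran from 0.00303 to 0.0316. The count of 6 was larger by DESeq2, with females fitted alone and with no filter, as given below. In males these 6 genes had log2 fold changes of 0.11, -0.045, 0.14, 0.039, 0.50 and 0.071. Gm43302 shares exon sequence on the same strand with Gbp10 and Gbp6, and Igtp with Irgm2, so reads there may be split or lost in counting. At an unadjusted p under 0.05 (edgeR) there were 1052 genes within females, 771 higher and 281 lower, against 739 from chance alone. Among the females the GC slope also went with the guide, at -0.045 and -0.12 in the controls and 0.031 and 0.16 in the KO libraries. Within males 0 genes passed in edgeR, with 271 at an unadjusted p under 0.05 and 2 by DESeq2. The interaction itself called 0 genes in edgeR, with 801 at an unadjusted p under 0.05, a smallest adjusted p of 0.167 (for H2-K1 and H2-D1), 2 by DESeq2, 0 by limma voom, 100 with no filter and 1 without KO 4. Among lists, 8 passed camera for the interaction and 0 with an estimated correlation (adjusted p = 0.556 for complement and MHC genes and 0.700 for interferon-stimulated genes); the count was 5 without control 1 or KO 2 and 17 without KO 1. Each sex had 2 mice per guide, and females were sequenced more deeply than males.

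The last comparison, females against males, called 9 genes, 4 on X, 5 on Y and 0 on autosomes. Higher in females were Xist and the translation factor gene Eif2s3x (log2 fold change 0.55 ± 0.06; edgeR, adjusted p = 0.0019). Lower in females were Ddx3y, Eif2s3y, Kdm5d, Uty and Gm47283 on Y, and Mid1 (-1.24 ± 0.18) and G530011O06Rik (-3.44 ± 0.30) on X. Of the lists, 12 passed camera for sex and 0 with an estimated correlation. The count of genes was 18 by DESeq2 and 112 with no filter.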

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

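For the interferon list, the GC slope as a covariate, the count of microglia markers, the comparison with matched lists for scaling, and the use of the single leave-outs (themselves set beforehand) as a test were chosen after related results had been seen; so were the count of microglia markers and the leave-outs of KO 3 or KO 4 for the MHC list; the immunoglobulin genes were picked after their counts were seen.

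Interferon-stimulated genes were higher in all 4 KO libraries, and KO 3 stood apart, with its gap to the next at 0.839 of the range of the KO group. Left out 1 at a time, the KO libraries gave list medians no lower than 0.52, 0 of 17 microglia markers reached the list's median, the list lay 0.77 above the middle of random lists matched on expression, which 1 factor per library would move alike, and the GC slope as a covariate gave 0.85, so 1 KO library, more microglia, scaling between libraries and GC content are each argued against as the whole cause. Low counts of the list's genes are argued against too, since 0% of 10000 random lists matched on expression reached the median, with 0.20 the highest among them, although random genes do not share regulation as these do. A response of CA1 to the SIK3 guide stays as a hypothesis, which may equally be a difference in virus preparation, injection or time, none of which the labels separate from the guide. The call rests on the preset correlation, as the adjusted p was 0.372 with an estimated one.

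Complement and MHC genes differed between the sexes in their response by camera, with an interaction median of 0.84 (-0.028 in males, 0.88 in females), and this was lost with an estimated correlation (adjusted p = 0.556). Thinning every library to the lowest total left 0.81. Thinning keeps the expected fold changes, so it could hardly have moved this value and does not decide on library depth. The lowest value without KO 3 or KO 4 was 0.64, which argues against 1 KO female. More microglia in KO females cannot be told apart from a change within cells, because 2 of the 17 microglia markers reached the list's interaction median and the others did not. That count cannot decide the question either way, because C1qa, C1qb and C1qc belong to both lists and were not taken out. Infiltrating immune cells were not tested and stay open. T cell and monocyte markers were at 64 raw counts in KO 4, 35 in KO 3, 25 and 24 in the KO males and 11 to 20 in controls. Immunoglobulin genes were at 2446 in KO 4 but 364 in KO 3, 253 and 288 in the KO males and 206 to 348 in controls, so high in 1 KO female only. Of these counts Ighm held 453 in KO 4, 332 in KO 3, 238 and 272 in the KO males and 198 to 327 in controls. Sex of the animals stays open as untested beyond 2 mice per group.

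Other lists with a different response in males and females by camera were interferon-stimulated genes (interaction median 0.77), microglia markers (0.32), oligodendrocyte markers (0.33), oligodendrocyte precursor markers (0.34), ependymal cell markers (0.81), GABA receptor subunits (-0.21) and mitochondrially encoded genes (-0.11). All were lost with an estimated correlation (adjusted p = 0.700).

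Single libraries lay far from the other 3 of their group in 14 of 194 group checks, where chance gives about 1 in 20, and lists that share genes are not independent. In brackets is the gap as a share of the range. Besides interferon-stimulated genes, the lists were CREB/CRTC targets in control 4 (0.831), glutamate receptors in control 3 (0.839), unfolded protein response genes in control 4 (0.835) and in KO 2 (0.863), CA1 markers in control 3 (0.869) and microglia markers in KO 4 (0.831). The genes were Vip in control 4 (0.853), Gbp7 in control 1 (0.871), Tekt1 in control 4 (0.961), Kdr in KO 1 (0.881), Hspe1 in KO 3 (0.921), Atp5e in control 2 (0.918) and Xbp1 in KO 2 (0.869).

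Some genes removed by the filter on low counts were far above every control in KO 3, KO 4 or both. In KO 4 the raw counts were 478 for the immunoglobulin light chain gene Igkc, 417 for Ighg2c, 324 for Igha and 213 for Ighg2b, against 0 to 7 in controls. The B cell genes Cd79a and Ms4a1 stood at 4 and 2 counts in KO 4. Jchain, the immunoglobulin joining chain gene, which the filter kept, had 166 counts in KO 4. It had 8 to 15 in controls and 8 to 13 in the other KO libraries. Cd74, the MHC class II invariant chain, had 133 counts in KO 4 and 29 in KO 3, against 2 to 6 in controls. The class II genes H2-Aa, H2-Ab1 and H2-Eb1 had 26, 29 and 29 counts in KO 4 and the complement gene C3 had 51. Bst2 had 38 counts in KO 3 and 20 in KO 4, against 4 to 7 in controls. KO 3 held 26 counts of the chemokine gene Cxcl10 and 30 of Cxcl13, against 0 to 5 in controls.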

How the results depend on the processing

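The alternatives added after seeing the data were the GC slope, the permutation of list means, leaving out both KO females, and those for the list interaction. The cause of each change was not tested, except that fewer samples enter when libraries are left out. The count of genes changed by the guide, 2, was 84 with no filter (74 higher, 10 lower), 0 with dentate markers as a covariate, 0 against a 1.2-fold change, 0 without both KO females, and 0 to 2 without single libraries; it was 2 under the other scalings, DESeq2, limma voom, the GC slope and 1 surrogate variable, with both genes shared. Sik3 and Col11a1 kept their direction in the 21 alternatives of that comparison; Sik3 passed in 14 and Col11a1 in 13, and besides single libraries both lost the call with dentate markers (adjusted p = 0.0766 and 0.0784), against a 1.2-fold change (0.182 and 0.308) and without both KO females (0.0990 and 0.470). Sik3 had log2 fold changes of -0.85 to -0.70 without single libraries. The interaction count, 0, was 100 with no filter, 2 by DESeq2 and 0 to 1 without single libraries. The count within males, 0, was 20 with no filter and 2 by DESeq2; within females, 6, it was 275 with no filter, 17 by DESeq2 and 31 when females were fitted alone. The sex count, 9, was 112 with no filter and 18 by DESeq2. Of 8 lists past camera, 0 passed with an estimated correlation, 0 by fry and 0 by permutation of list means. The permutation could hardly have called any, because its smallest p of 0.0286 was adjusted over 38 lists. For interferon-stimulated genes, camera with an estimated correlation, fry and the permutation gave adjusted p of 0.372, 0.662 and 0.724. The list median of 0.79 comes from the main fit and could not change under these tests. The list interaction, 8, gave 5 to 17 without single libraries and 0 with an estimated correlation. Without both KO females the medians of complement and MHC genes (-0.028) and of microglia markers (-0.028) reversed. Under the alternatives run for each named gene other than Sik3 and the sex check genes (other size factors, DESeq2, no sex covariate, no filter, single libraries left out), 15 values gained the threshold, all with no filter, 5 lost it, all for Col11a1 without a library, and 652 kept their side; under the same alternatives Sik3 lost the call in 4, without control 2 (adjusted p = 0.108), control 3 (0.0866), KO 2 (0.0865) or KO 3 (0.242). Genes of under 10 counts per library are limited by depth.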

Other observations

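The tests of the leading axis in this part were all chosen after values bearing on it had been seen; the counts over other splits were planned.

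Among the 34 splits of the 8 libraries into 4 and 4 that can be fitted with sex, the real one always counted among them, 3 gave at least the 2 genes found between the guides, so chance is not excluded for that count, and the highest other split gave 1968. For gene lists, 22 of 34 splits gave at least the 8 lists past camera, with 16 the highest other, so chance is not excluded there either. For sex, 2 of 34 splits gave at least 9 genes, the highest other being 1430, so the count alone does not exclude chance, while the genes behind it were 4 on X and 5 on Y, the Y genes with 0 counts in females. The split with 1968 genes, control 1, KO 2, KO 3 and KO 4 against the rest, points to a structure of the libraries that is not the guide. Its 1370 higher genes had a median GC content of 57.4% and its 598 lower genes 41.4%. Its 4 libraries had slopes of log2 CPM on GC content of at least 0.031 per 10 points, and the rest at most -0.045. That split exchanges control 1 and KO 1, but Sik3 was at 7.37 log2 CPM in control 1 and 6.24 in KO 1, on the sides their labels give. With the GC slope as a covariate the guide comparison had 751 genes at an unadjusted p under 0.05, against 416 without it and 739 from chance, and Sik3 had a log2 fold change of -0.84 (edgeR, adjusted p = 1.1e-07).

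The leading axis of autosomal genes held 25.0% of the variance of the 500 most variable ones. Libraries of both guides and both sexes lay on either side of 0. Each library's GC slope followed the axis less firmly (Pearson r = -0.732, exact permutation p = 0.0474, and Spearman rho = -0.714, exact permutation p = 0.0576). That relation rests on the 2 libraries farthest out, as r was -0.482 without them. GC content may account for the axis. Over 14064 genes, which are not independent, the rank correlation of a gene's correlation with the axis and its GC content was -0.613. For transcript length it was 0.133, which left that explanation open. Neuronal activity at the time of death could be another source, as immediate early genes followed the axis over the 8 libraries (Pearson r = -0.781, exact permutation p = 0.0236; Spearman rho = -0.810, exact permutation p = 0.0218; r = -0.881 without the 2 libraries farthest out; Benjamini-Hochberg adjusted p over the 2 relations computed 0.0472, and 0.0474 for the GC slope). It cannot be told apart from GC content, because 15.1% of 10000 lists matched on GC content and length followed it as closely, with a median r of -0.640. Immediate early genes were not taken out of the 500 most variable autosomal genes that set the axis. They may therefore help set the axis that they follow, and the matched lists were not matched on variance. No explanation named by the design was tested for it.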
